A study of Homo sapiens with 6 samples.

How the data were processed

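The series holds 6 RNA sequencing samples of HaCaT cells, 3 labelled control and 3 labelled lapatinib, each at 24 h. Per the labels' protocols, total RNA was taken with TRIzol and libraries were made with an Illumina TruSeq RNA kit. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8. That build is a mouse build, whereas the gene identifiers in the files are human Ensembl identifiers, so the build behind the values is unclear and no coordinates are given. The counting program, strandedness and handling of reads that match more than 1 place are not given in the sources used here. The deposited values are FPKM, per the file headers, with 0.0001 as the lowest value, and no whole-number counts were used here. The file of lapatinib replicate 1 repeats gene names in the place of values, so that sample was not analysed here and the comparison rests on 3 control and 2 lapatinib libraries.

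FPKM summed to 358272, 353306 and 336437 in control replicates 1 to 3 and to 349504 and 372346 in lapatinib replicates 2 and 3. Low FPKM values of genes with a single annotated transcript tend to fall on steps of 1 fragment. The step size puts the depth at 22.5, 23.7 and 24.3 M fragments for control replicates 1 to 3 and at 23.9 and 22.7 M fragments for lapatinib replicates 2 and 3. The step was sought only within a preset window, so a depth far from these values could not have been found. Only 29.1 to 33.8% of such low values lay within 0.05 of a whole step, so counts were not rebuilt and the depths are approximate. Of 60612 gene identifiers, 58394 (96.34%) were found by Ensembl identifier in GENCODE 29, which was used for gene type, length, GC content and exon overlap only.

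FPKM were transformed to log2(FPKM + 1) without further scaling, and genes with a mean of at least 1 FPKM over the 5 libraries were tested, 11744 in all. Lapatinib was compared with control by a linear model in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes, a threshold of 0.05 and 3 residual degrees of freedom. A gene counted as changed at least 2-fold where the absolute log2 fold change was also at least 1. Figures were drawn with Python 3.11.15. The comparison, gene lists, tests, thresholds and the first set of alternatives were chosen before the data were examined, for all 6 samples. Lapatinib replicate 1 was dropped, and the filter set over 5 libraries, only once its file proved to hold no values.

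A total of 44 gene lists were written from general knowledge, among them pro-apoptotic BCL2 family members, anti-apoptotic BCL2 family members and inhibitors of apoptosis, caspases and mitochondrially released death factors, death receptor pathway, proteins encoded by the mitochondrial genome, nuclear-encoded subunits of respiratory complex I, nuclear-encoded subunits of respiratory complexes II and III, nuclear-encoded subunits of respiratory complex IV, nuclear-encoded subunits of ATP synthase, tricarboxylic acid cycle enzymes, mitochondrial genome maintenance and biogenesis, mitochondrial fusion, fission and mitophagy, mitochondrial chaperones and proteases, homologous recombination and Fanconi anaemia genes, non-homologous end joining, excision and mismatch repair, DNA damage sensing and checkpoint signalling, DNA replication, G2 and mitosis, ERK pathway target and feedback genes, ERBB receptors and ligands, genes raised when PI3K and AKT signalling falls, cholesterol synthesis and uptake, fatty acid synthesis, suprabasal and cornified-layer keratinocyte genes, basal keratinocyte genes, stress and simple-epithelial keratins, epidermal cytokines, chemokines and alarmins, interferon-stimulated genes, ATF4 and integrated stress response targets, endoplasmic reticulum chaperones and unfolded protein response, NRF2 targets and antioxidant enzymes, glycolysis and hypoxia-induced genes, aryl hydrocarbon receptor targets, cytosolic heat shock proteins, lysosome and autophagy genes, ribosome biogenesis, mesenchymal and extracellular matrix genes, epithelial junction genes, fibroblast markers, melanocyte markers, leukocyte and endothelial markers and cytosolic ribosomal proteins. Lists with at least 5 tested members, 41 in all, were tested against the other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the rotation test fry were run beside it. Fry asks whether the members of a list changed at all, without comparing them with the other genes. Counts of members that rose or fell use the adjustment over all tested genes, and a second count adjusts over the list alone.

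Genes were named by a rule. It takes the 10 largest rises and 10 largest falls among changed genes with no overlap between groups and a mean of at least 5 FPKM in the higher group. It adds up to 4 changed members of each list with the smallest p in the direction most of them took, the 2 highest members where fewer than 2 changed, and a set fixed in advance that includes EGFR, ERBB2, ERBB3, ERBB4, BAX, BCL2, H2AX, CDKN1A and GADD45A. Some genes and 1 list that the rule or the lists cover are not reported here, although they stay in all tests and counts. Changed members of lists in which 5 or fewer moved 1 way, and H2BC5, H2BC21, H2AW, H1-2, B2M and MYC, were added after their values were seen.

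Simulated values were normal, with variances drawn from the prior that limma fitted to the real libraries. The gene test was tested on them with 200 changed genes among 11744 and 10 draws. It recovered 1.34% of genes changed by 0.5 on the log2 scale, 50.9% of those changed by 1 and 92.9% of those changed by 2, and 5.31% of the genes it called had not been changed. Lists without a planted change were called 0.2 times per draw, and a planted list fall of 0.5 was called in 100% of draws. With 200 changed genes the adjustment is stricter than with the 5308 called here, so the shares recovered do not carry over to the real comparison. Simulated genes were independent and met the assumptions of the test. The gene and list figures therefore leave out correlation between genes and shifts shared by many genes of a library.

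Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, median-ratio rescaling, quantile normalization, TPM, array weights, eBayes without trend and with robust estimation, the replicate number as a block, and each library left out in turn. Leaving out mitochondrial genes, keeping protein-coding genes only and leaving out genes that share exons on the same strand were added after seeing the data. Nuclear and mitochondrially encoded respiratory chain subunits were compared by permuting genes 100000 times. Groups of genes with a shared symbol stem and at least 15 tested members, 64 in all, were tested with camera after seeing the data.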

Results

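Transcript levels were measured by RNA sequencing in HaCaT cells, an immortalised line of human epidermal keratinocytes, 24 h after treatment with lapatinib, an inhibitor of the EGFR and ERBB2 tyrosine kinases, or under control conditions. The series labels 3 control and 3 lapatinib samples. Expression values were read for 3 control and 2 lapatinib libraries, and lapatinib replicate 1 was not analysed here. The drug dose and the composition of the control medium are not given in the sources used here. Each library lists FPKM, fragments per kilobase of transcript scaled to the mapped fragments, for 60612 genes. Of these, 59.0 to 62.1% stood at the floor value of 0.0001 in each library. A mean of at least 1 FPKM over the 5 libraries was reached by 11744 genes, which were tested. FPKM summed to between 336437 and 372346 per library. The spacing of low values, sought within a preset window, puts the depth at about 22.5 to 24.3 M fragments per library.

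Log2 values of the tested genes correlated across genes at 0.964 to 0.976 between libraries of 1 group and at 0.820 to 0.893 between groups. The first principal component, with 78.6% of the variance, separated the 3 control libraries from the 2 lapatinib libraries. Genes of the mitochondrial genome took 43.5, 42.4 and 39.4% of all FPKM in the control libraries and 44.4 and 47.9% in the lapatinib libraries. Values below are mean ± SD of FPKM over 3 control and 2 lapatinib libraries. Log2 fold changes, given in brackets as log2, are lapatinib minus control on the log2(FPKM + 1) scale. This scale understates the change of low genes. Adjusted p values for genes are from limma. A number alone in brackets after a gene is its log2 fold change. Where a gene lost its call without any of several single libraries, the highest adjusted p is given with that library. Members named because 5 or fewer of a list moved 1 way were chosen after their values were seen.

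The title of the series ties the death of lapatinib-treated keratinocytes to mitochondria and damaged DNA, and the comparison asked which transcripts of these and other processes differed after 24 h of the drug. All 42 tested genes of the DNA replication list fell, although its call by camera (adjusted p = 1.70e-15) was lost with an estimated correlation (adjusted p = 0.502). MCM6, a subunit of the replicative helicase, went from 40.3 ± 4.29 to 2.85 ± 0.996 FPKM (log2 −3.44, adjusted p = 0.000884). All 26 tested genes of ribosome biogenesis fell too, with the same loss of the list call (adjusted p = 2.08e-09 and 0.502). NOLC1, a nucleolar chaperone gene among them, went from 48.1 ± 5.26 to 9.21 ± 0.543 FPKM (log2 −2.26, adjusted p = 0.000957). The ERK phosphatase gene DUSP6 fell from 13.4 ± 2.67 to 0.252 ± 0.116 FPKM (log2 −3.51, adjusted p = 0.000881). In the opposite direction, PIK3IP1, an inhibitor of PI3K, rose from 3.60 ± 1.51 to 71.5 ± 14.1 FPKM (log2 4.03, adjusted p = 0.00112). In all, 5308 of 11744 genes changed at adjusted p under 0.05, of which 2172 were higher and 3136 lower with lapatinib. A change of at least 2-fold was found for 1853 genes, 733 higher and 1120 lower. Lapatinib and control values did not overlap for any of the 5308, and 68.9% of all tested genes showed no overlap, where chance gives 20%. The labels do not say that replicates came from separate cultures, so the p values measure only the spread between these samples. Without lapatinib replicate 2, with the lone lapatinib library assumed to vary like the controls, 2875 genes passed.

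The receptors that lapatinib binds were higher at the transcript level. EGFR (ENSG00000146648) rose from 26.1 ± 0.175 to 38.6 ± 5.77 FPKM (log2 0.54, adjusted p = 0.0183), although this call was lost without control replicate 2 (adjusted p = 0.0645) and without lapatinib replicate 3 (adjusted p = 0.101). ERBB2 (ENSG00000141736) rose from 8.66 ± 0.639 to 14.2 ± 2.18 FPKM (log2 0.65, adjusted p = 0.0113), with adjusted p = 0.0803 without lapatinib replicate 2. ERBB3 (ENSG00000065361), a receptor with little kinase activity of its own, rose from 3.61 ± 0.415 to 10.04 ± 1.13 FPKM (log2 1.26, adjusted p = 0.00155). ERBB4 was listed at 0.0147 ± 0.00420 and 0.0494 ± 0.0382 FPKM and was not tested. Among ERBB receptors and ligands, 4 of 9 tested members rose and 4 fell (4 and 4 adjusted over the list alone). The ligand gene NRG2 rose from 0.780 ± 0.363 to 4.96 ± 0.178 FPKM (log2 1.76). TGFA (−0.94 on the log2 scale), AREG (−1.68), HBEGF (−0.99; adjusted p = 0.0738 without lapatinib replicate 2) and the feedback inhibitor gene ERRFI1 (−1.64) fell. The list as a whole did not move against the other genes (adjusted p = 0.976 by camera).

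Targets and feedback inhibitors of the ERK pathway fell as a group. In this list 11 of 15 tested members fell and 1 rose (11 and 1 adjusted over the list alone, and with all genes adjusted 2 rises without control replicate 3), with a median log2 fold change of −1.21 (adjusted p = 0.00129 by camera, adjusted p = 0.502 with an estimated correlation). PHLDA1 fell from 14.7 ± 2.31 to 2.03 ± 0.0295 FPKM (log2 −2.36, adjusted p = 0.000965) and CCND1, which encodes cyclin D1, from 64.0 ± 10.9 to 14.4 ± 2.24 FPKM (log2 −2.07, adjusted p = 0.00114). The RAS inhibitor gene SPRED2 fell from 6.81 ± 1.17 to 1.94 ± 0.169 FPKM (log2 −1.40). FOSL1, a component of AP-1, fell from 19.4 ± 15.2 to 0.718 ± 0.271 FPKM (log2 −3.33). The member that rose was EPHA4, from 0.139 ± 0.0259 to 3.57 ± 2.32 FPKM (log2 1.90). Genes known to rise when PI3K and AKT signalling falls went up. Of these, 10 of 13 tested members rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.24 (adjusted p = 4.68e-06, adjusted p = 0.502 with an estimated correlation). The ubiquitin ligase gene FBXO32 rose from 1.91 ± 0.343 to 28.0 ± 6.78 FPKM (log2 3.30, adjusted p = 0.000918). The transcriptional repressor gene BCL6 rose from 2.17 ± 0.343 to 9.95 ± 0.676 FPKM (log2 1.79, adjusted p = 0.00112) and YPEL3 from 2.36 ± 0.961 to 17.9 ± 3.46 FPKM (log2 2.53).

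**Figure D1:**
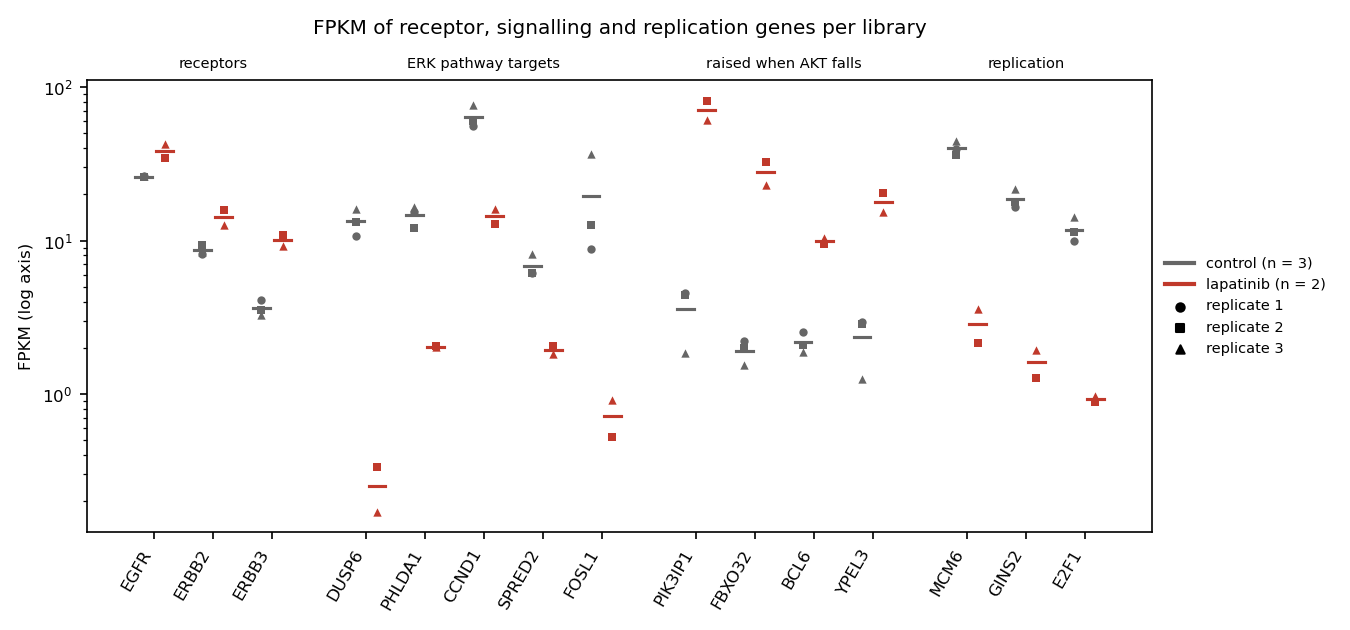
FPKM on a log axis of receptor, ERK target, AKT-repressed and replication genes in each library, with control in grey (n = 3), lapatinib in red (n = 2), a bar at each mean and symbols for the replicate number. DUSP6 averaged 13.4 FPKM in control and 0.252 FPKM in lapatinib libraries, and PIK3IP1 3.60 and 71.5 FPKM.

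All 42 tested members of the DNA replication list fell (42 adjusted over the list alone), with a median log2 fold change of −1.85 (adjusted p = 1.70e-15 by camera, adjusted p = 0.502 with an estimated correlation). GINS2, part of the helicase complex, fell from 18.7 ± 2.60 to 1.61 ± 0.466 FPKM (log2 −2.92, adjusted p = 0.000957) and the transcription factor gene E2F1 from 11.8 ± 2.17 to 0.926 ± 0.0557 FPKM (log2 −2.72, adjusted p = 0.000957). For genes of G2 and mitosis, 30 of 32 tested members fell and 0 rose (31 and 0 adjusted over the list alone), and the median was −1.23 (adjusted p = 5.61e-08, adjusted p = 0.521 with an estimated correlation). The proliferation marker MKI67 fell from 32.7 ± 3.70 to 11.3 ± 2.88 FPKM (log2 −1.47) and the cyclin A gene CCNA2 from 53.5 ± 2.59 to 17.1 ± 6.68 FPKM (log2 −1.64). The spindle checkpoint kinase gene BUB1B went from 22.8 ± 3.07 to 6.34 ± 2.49 FPKM (log2 −1.73). Ribosome biogenesis genes fell in 26 of 26 cases (26 adjusted over the list alone), with a median of −1.52 (adjusted p = 2.08e-09, adjusted p = 0.502 with an estimated correlation). NOP56, a core protein of small nucleolar ribonucleoproteins, fell from 37.9 ± 7.75 to 7.88 ± 0.696 FPKM (log2 −2.12), and WDR43 from 21.1 ± 3.14 to 5.52 ± 0.759 FPKM (log2 −1.76). The cytosolic ribosomal proteins themselves differed little: 2 of 41 tested members fell and 1 rose (0 and 0 adjusted over the list alone, and with all genes adjusted 0 rises without control replicate 1 or 2 or 3 or lapatinib replicate 2 and 1 fall without control replicate 2 or lapatinib replicate 2 or 3), and the list did not stand apart (adjusted p = 0.976). Their median of −0.06 changed sign with median-ratio rescaling (0.03). RPL35 fell from 762 ± 14.2 to 529 ± 5.63 FPKM (log2 −0.52) and so did RPL27 (log2 fold change −0.42; adjusted p = 0.0919 without lapatinib replicate 2), while RPLP1 rose by 0.53 (log2 0.35 and adjusted p = 0.127 without lapatinib replicate 2).

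Nuclear genes for the mitochondrial respiratory chain fell, while the transcripts of the mitochondrial genome did not. Of the subunits of complex I, 28 of 37 tested members fell and 0 rose (31 and 0 adjusted over the list alone, and with all genes adjusted 17 falls without lapatinib replicate 2). Among them NDUFS5 went from 235 ± 1.81 to 87.4 ± 18.2 FPKM (log2 −1.43) and NDUFAB1 from 31.0 ± 0.920 to 12.5 ± 1.29 FPKM (log2 −1.25). For complexes II and III, 12 of 13 tested members fell and 0 rose (12 and 0 adjusted over the list alone, and with all genes adjusted 7 falls without lapatinib replicate 2). Cytochrome c1 (CYC1) went from 122 ± 17.96 to 37.7 ± 5.999 FPKM (log2 −1.67, adjusted p = 0.00149). In complex IV 7 of 10 tested members fell and 0 rose (8 and 0 adjusted over the list alone, and with all genes adjusted 3 falls without lapatinib replicate 2). One of them, COX7B, went from 46.3 ± 1.14 to 21.9 ± 4.80 FPKM (log2 −1.06). In ATP synthase 12 of 15 tested members fell and 0 rose (12 and 0 adjusted over the list alone). ATP5MC1 went from 21.2 ± 3.22 to 3.91 ± 1.07 FPKM (log2 −2.19, adjusted p = 0.00114). Medians were −0.70, −0.69, −0.59 and −0.88, with camera adjusted p = 2.42e-07, 0.000142, 0.00486 and 0.000285 in the same order, and adjusted p = 0.502 with an estimated correlation for each of the 4. Of the 13 proteins encoded by the mitochondrial genome, MT-ND1 rose from 5805 ± 447 to 8532 ± 1512 FPKM (log2 0.55), with adjusted p = 0.121 without lapatinib replicate 2, adjusted p = 0.0773 without control replicate 1 and adjusted p = 0.0727 without control replicate 2, and the other 12 did not pass, though 1 of them rose without lapatinib replicate 2 (0 of 13 adjusted over the list alone, and with all genes adjusted 1 fall without lapatinib replicate 3; adjusted p = 0.436 by camera). MT-CO2 stood at 22862 ± 3010 FPKM in control and 23213 ± 3718 FPKM in lapatinib libraries. The median of this list was 0.02 and turned negative with TPM (−0.03) and quantile normalization (−0.09). The medians of the 75 nuclear subunits and the 13 mitochondrial ones differed by −0.72 (permutation test over genes, p = 1e-05, the smallest that 100000 permutations can give), and genes are not independent replicates. The share of FPKM from mitochondrial genes was higher in both lapatinib libraries than in any control library. With those genes left out and the rest rescaled, an alternative chosen after seeing the data, 5253 genes changed.

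Other mitochondrial genes fell as well. Tricarboxylic acid cycle enzymes had a median of −0.83: 14 of 17 tested members fell and 0 rose (15 and 0 adjusted over the list alone, and with all genes adjusted 8 falls without lapatinib replicate 2; adjusted p = 4.86e-05, adjusted p = 0.502 with an estimated correlation). Fumarase (FH) went from 78.3 ± 4.54 to 32.9 ± 0.312 FPKM (log2 −1.22) and IDH3A from 7.48 ± 0.427 to 2.19 ± 0.202 FPKM (log2 −1.41). Mitochondrial chaperones and proteases had a median of −0.77: 10 of 13 tested members fell and 1 rose (10 and 1 adjusted over the list alone, and with all genes adjusted 0 rises without lapatinib replicate 2; adjusted p = 0.00345, adjusted p = 0.502 with an estimated correlation). The chaperonin gene HSPD1 fell from 153 ± 24.5 to 27.8 ± 6.62 FPKM (log2 −2.43, adjusted p = 0.00112) and HSPA9 from 49.5 ± 6.48 to 12.6 ± 1.82 FPKM (log2 −1.90). ATF5, a transcription factor of the mitochondrial stress response, was the member that rose (0.86; adjusted p = 0.0871 without lapatinib replicate 2). For mitochondrial genome maintenance and biogenesis, 6 of 13 tested members fell and 0 rose (6 and 0 adjusted over the list alone; adjusted p = 0.00768, adjusted p = 0.502 with an estimated correlation). TFAM, which packages mitochondrial DNA, went from 10.8 ± 0.933 to 4.64 ± 0.174 FPKM (log2 −1.06) and the coactivator gene PPRC1 from 9.12 ± 2.94 to 1.72 ± 0.112 FPKM (log2 −1.86). Genes of mitochondrial fusion, fission and mitophagy went both ways. There 6 of 14 tested members fell and 4 rose (7 and 4 adjusted over the list alone, and with all genes adjusted 3 falls without control replicate 2 or lapatinib replicate 2), with a median of −0.37, a mean of 0.03 and no call (adjusted p = 0.790). MFN2, which fuses outer membranes, fell from 17.0 ± 1.26 to 9.69 ± 1.26 FPKM (log2 −0.76) and BNIP3 from 2.63 ± 0.409 to 0.425 ± 0.0471 FPKM (log2 −1.34). The mitophagy genes PINK1 (1.997), SQSTM1 (1.65) and OPTN (1.70) rose, as did MIEF1 (0.48; adjusted p = 0.129 without lapatinib replicate 2).

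Genes of cell death changed one by one, and none of the 4 lists passed camera, while the rotation test fry called the caspase list lower. Among pro-apoptotic BCL2 family members, 2 of 9 tested members fell and 1 rose (2 and 1 adjusted over the list alone, and with all genes adjusted 2 rises without lapatinib replicate 3 and 1 fall without lapatinib replicate 2). BMF, a BH3-only protein, rose from 0.766 ± 0.502 to 7.87 ± 0.284 FPKM (log2 2.37, adjusted p = 0.00150), while BID fell from 9.85 ± 1.016 to 3.86 ± 0.0692 FPKM (log2 −1.15, adjusted p = 0.00159) and BOK from 8.31 ± 1.19 to 4.23 ± 0.447 FPKM (log2 −0.83), with adjusted p = 0.0520 without lapatinib replicate 2 for BOK. BAX averaged 14.9 ± 2.90 FPKM in control and 10.6 ± 0.723 FPKM in lapatinib libraries and did not pass (adjusted p = 0.0817; adjusted p = 0.0383 without control replicate 1). The median of this list was −0.04, its mean 0.10 and its adjusted p = 0.930, and the median turned positive with median-ratio rescaling (0.05) and quantile normalization (0.13). Of anti-apoptotic BCL2 family members and inhibitors of apoptosis, 3 of 6 tested members rose and 1 fell (3 and 1 adjusted over the list alone, and with all genes adjusted 1 rise without control replicate 2 or lapatinib replicate 3 and 0 rises without lapatinib replicate 2; adjusted p = 0.346). MCL1 rose from 62.5 ± 10.7 to 90.9 ± 3.39 FPKM (log2 0.55), with adjusted p = 0.150 without lapatinib replicate 2. BIRC2 rose from 6.61 ± 3.19 to 16.6 ± 1.31 FPKM (log2 1.28), with adjusted p = 0.0969 without lapatinib replicate 2, and BIRC3 from 2.29 ± 0.352 to 4.24 ± 0.765 FPKM (log2 0.67), with adjusted p = 0.0977 without lapatinib replicate 2. BIRC5, the mitotic inhibitor of apoptosis survivin, fell from 8.89 ± 1.82 to 3.11 ± 0.464 FPKM (log2 −1.26). BCL2 stood at 0.0582 ± 0.0293 FPKM in control and at 0.00713 and 0.0001 FPKM in the lapatinib libraries, below the filter.

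Among caspases and mitochondrially released death factors, 5 of 14 tested members fell and 0 rose (5 and 0 adjusted over the list alone, and with all genes adjusted 1 rise without control replicate 2 or lapatinib replicate 3 and 3 falls without lapatinib replicate 3; adjusted p = 0.173 by camera and adjusted p = 0.00800 as lower by fry). CYCS, cytochrome c, fell from 42.1 ± 5.41 to 7.83 ± 1.91 FPKM (log2 −2.30, adjusted p = 0.00112). The DNA repair enzyme and caspase substrate PARP1 fell from 48.8 ± 4.37 to 17.4 ± 1.83 FPKM (log2 −1.44, adjusted p = 0.00119) and AIFM1 from 8.50 ± 0.239 to 4.13 ± 0.959 FPKM (log2 −0.90). DFFA (−0.59; adjusted p = 0.102 without lapatinib replicate 3) and CASP8 (−0.44; adjusted p = 0.168 without lapatinib replicate 2) fell to a lesser extent. In the death receptor pathway 4 of 9 tested members rose and 3 fell (4 and 4 adjusted over the list alone, and with all genes adjusted 2 rises without lapatinib replicate 2 or 3), with a median of −0.36, a mean of 0.17 and adjusted p = 0.907. TNFSF10, the ligand TRAIL, rose from 25.9 ± 12.6 to 248 ± 65.6 FPKM (log2 3.33, adjusted p = 0.00308) and the TNF receptor gene TNFRSF1A from 26.3 ± 3.65 to 52.97 ± 7.39 FPKM (log2 0.99, adjusted p = 0.00483). TRADD (0.54; adjusted p = 0.0667 without lapatinib replicate 3) and RIPK1 (0.44; adjusted p = 0.168 without lapatinib replicate 2) also rose. TNFRSF10A, a receptor for TRAIL, fell from 4.97 ± 1.37 to 1.27 ± 0.212 FPKM (log2 −1.37), and so did TNFRSF10B (−0.47; adjusted p = 0.122 without lapatinib replicate 3) and the adaptor gene FADD (−0.89).

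Of the 4 lists of DNA repair and damage sensing, 2 passed camera, both as lower. The replication and mitosis lists fell as well, and whether repair genes fell apart from them was not tested. For homologous recombination and Fanconi anaemia genes, 22 of 28 tested members fell and 1 rose (22 and 1 adjusted over the list alone, and with all genes adjusted 0 rises without control replicate 2 or 3 or lapatinib replicate 2 or 3), with a median of −1.002 (adjusted p = 2.55e-06, adjusted p = 0.502 with an estimated correlation). The nuclease gene EXO1 fell from 12.7 ± 0.306 to 1.16 ± 0.759 FPKM (log2 −2.71, adjusted p = 0.00112) and the helicase gene BLM from 5.24 ± 0.268 to 0.694 ± 0.263 FPKM (log2 −1.89, adjusted p = 0.00111). FANCF was the one that rose (0.43; adjusted p = 0.192 without lapatinib replicate 2). For DNA damage sensing and checkpoint signalling, 11 of 20 tested members fell and 0 rose (11 and 0 adjusted over the list alone, and with all genes adjusted 7 falls without lapatinib replicate 2 or 3; adjusted p = 0.00700, adjusted p = 0.502 with an estimated correlation), a call that ended among genes of mean FPKM of at least 5 (adjusted p = 0.224). The checkpoint kinase gene CHEK1 fell from 8.61 ± 0.526 to 1.57 ± 0.465 FPKM (log2 −1.91, adjusted p = 0.00112) and CLSPN from 3.25 ± 0.472 to 0.319 ± 0.217 FPKM (log2 −1.69). H2AX, the histone variant phosphorylated at DNA breaks, fell from 92.3 ± 16.7 to 29.1 ± 13.1 FPKM (log2 −1.69, adjusted p = 0.00592). In non-homologous end joining 5 of 10 tested members fell and 1 rose (5 and 1 adjusted over the list alone, and with all genes adjusted 0 rises without control replicate 1 or 2 or lapatinib replicate 2 or 3; adjusted p = 0.411 by camera and adjusted p = 0.00478 as lower by fry). PRKDC fell from 20.3 ± 0.746 to 7.86 ± 0.266 FPKM (log2 −1.27) and XRCC6 from 194 ± 5.004 to 86.7 ± 11.4 FPKM (log2 −1.16). POLL rose (0.40; adjusted p = 0.1998 without lapatinib replicate 2). In excision and mismatch repair 12 of 29 tested members fell and 4 rose (13 and 4 adjusted over the list alone, and with all genes adjusted 2 rises without control replicate 2 or 3 and 1 rise without lapatinib replicate 2; adjusted p = 0.118 by camera and adjusted p = 0.00478 as lower by fry). The uracil glycosylase gene UNG fell from 28.2 ± 4.46 to 8.42 ± 0.757 FPKM (log2 −1.62). XPC, which recognises damage for nucleotide excision repair, rose from 5.94 ± 0.169 to 14.9 ± 2.72 FPKM (log2 1.19).

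CDKN1A, the cell cycle inhibitor p21, rose from 13.8 ± 1.96 to 52.2 ± 11.5 FPKM (log2 1.84, adjusted p = 0.00143). The stress-induced gene GADD45A averaged 15.3 ± 1.60 FPKM in control and 13.6 ± 2.68 FPKM in lapatinib libraries and did not pass (adjusted p = 0.418).

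**Figure D2:**
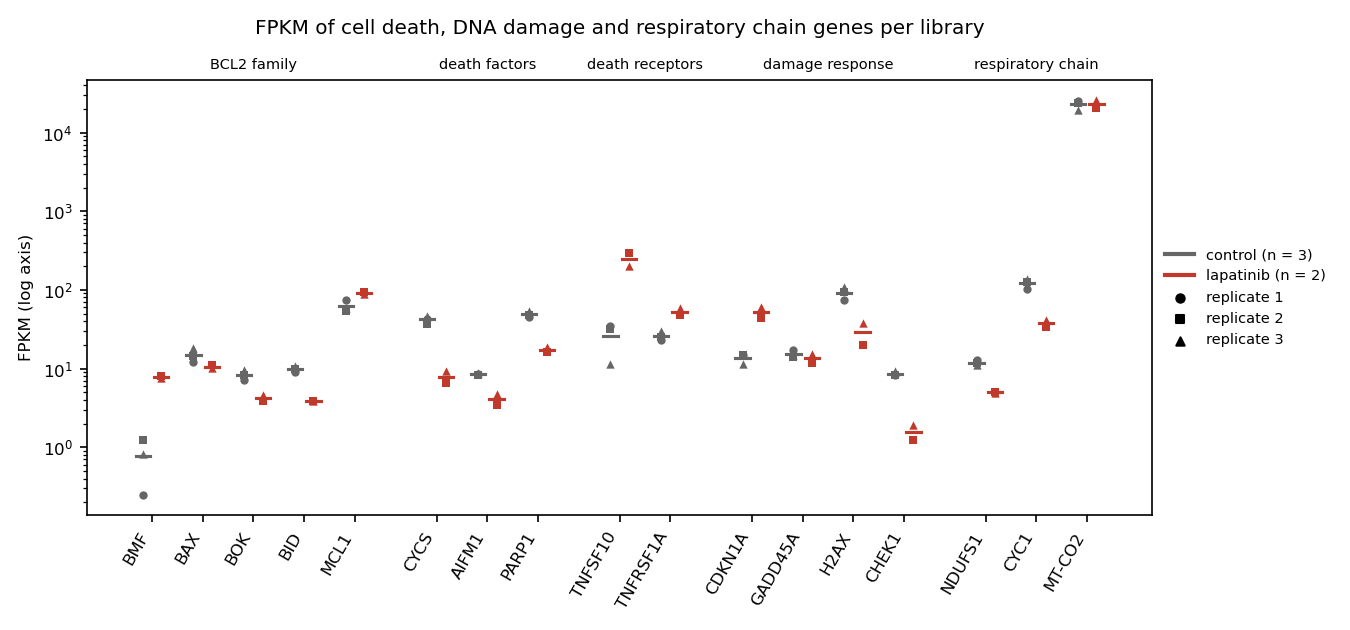
FPKM on a log axis of BCL2 family, death factor, death receptor, DNA damage and respiratory chain genes in each library, with control in grey (n = 3), lapatinib in red (n = 2), a bar at each mean and symbols for the replicate number. CYCS averaged 42.1 FPKM in control and 7.83 FPKM in lapatinib libraries, TNFSF10 25.9 and 248 FPKM, and MT-CO2 22862 and 23213 FPKM.

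Chaperones and glycolytic enzymes fell. For cytosolic heat shock proteins, 7 of 11 tested members fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 0.00331, adjusted p = 0.516 with an estimated correlation). HSP90AB1 went from 778 ± 107 to 179 ± 40.5 FPKM (log2 −2.12, adjusted p = 0.00114) and HSP90AA1 from 275 ± 28.3 to 65.3 ± 2.36 FPKM (log2 −2.05). For endoplasmic reticulum chaperones and the unfolded protein response, 12 of 19 tested members fell and 1 rose (12 and 1 adjusted over the list alone, and with all genes adjusted 2 rises without control replicate 1 and 0 rises without lapatinib replicate 2 or 3; adjusted p = 0.00713, adjusted p = 0.516 with an estimated correlation). HSPA5, the main chaperone of that compartment, fell from 251 ± 2.70 to 93.0 ± 6.36 FPKM (log2 −1.42, adjusted p = 0.00112), and HERPUD1 rose (0.59; adjusted p = 0.0650 without lapatinib replicate 3). For glycolysis and hypoxia-induced genes, 14 of 24 tested members fell and 3 rose (15 and 3 adjusted over the list alone; adjusted p = 0.00345, adjusted p = 0.521 with an estimated correlation). ENO1 went from 233 ± 18.5 to 55.1 ± 6.35 FPKM (log2 −2.06, adjusted p = 0.000965) and TPI1 from 291 ± 18.7 to 78.8 ± 18.02 FPKM (log2 −1.89). The 3 that rose were ADM (1.84), SLC16A3 (0.87) and PFKFB3 (0.55; adjusted p = 0.158 without lapatinib replicate 2). ATF4 and integrated stress response targets were not called as a list (adjusted p = 0.398): 9 of 19 tested members fell and 4 rose (9 and 4 adjusted over the list alone). PSAT1, an enzyme of serine synthesis, fell from 93.8 ± 28.5 to 13.2 ± 2.503 FPKM (log2 −2.71, adjusted p = 0.00119) and MTHFD2, of mitochondrial folate metabolism, from 15.1 ± 4.19 to 3.58 ± 0.639 FPKM (log2 −1.79). SESN2 (0.90) and DDIT4 (0.61) rose. Among NRF2 targets and antioxidant enzymes, 10 of 24 tested members fell and 4 rose (10 and 5 adjusted over the list alone, and with all genes adjusted 2 rises without lapatinib replicate 3 and 5 falls without lapatinib replicate 2; adjusted p = 0.717). TXN went from 547 ± 19.7 to 229 ± 54.4 FPKM (log2 −1.27) and PRDX1 from 445 ± 17.8 to 232 ± 41.4 FPKM (log2 −0.94), while GPX2 rose by 0.88. Of aryl hydrocarbon receptor targets, 2 of 6 tested members rose and 2 fell (2 and 2 adjusted over the list alone, and with all genes adjusted 0 falls without control replicate 2 or lapatinib replicate 2 and 1 fall without control replicate 3 or lapatinib replicate 3; adjusted p = 0.496). CYP1A1 rose from 0.887 ± 0.386 to 6.42 ± 3.29 FPKM (log2 1.92) and ALDH3A1 from 34.7 ± 8.21 to 121 ± 12.2 FPKM (log2 1.80, adjusted p = 0.00209), whereas NQO1 (−0.78; log2 −0.48 and adjusted p = 0.0968 without lapatinib replicate 2) and AHR itself (−0.50; adjusted p = 0.0741 without lapatinib replicate 3) fell.

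Lists of lysosomal and sterol genes were called higher. In the lysosome and autophagy list 12 of 28 tested members rose and 1 fell (12 and 1 adjusted over the list alone, and with all genes adjusted 0 falls without lapatinib replicate 2), with a median of 0.40 (adjusted p = 0.000716, adjusted p = 0.502 with an estimated correlation). The cathepsin gene CTSA rose from 30.7 ± 3.24 to 92.1 ± 14.6 FPKM (log2 1.55, adjusted p = 0.00136) and CTSB from 45.9 ± 4.98 to 126 ± 26.9 FPKM (log2 1.43). NPC1, a lysosomal cholesterol transporter, rose from 5.28 ± 0.455 to 12.5 ± 1.38 FPKM (log2 1.10). The galactosidase gene GLA fell (−0.70; adjusted p = 0.0814 without lapatinib replicate 2). For cholesterol synthesis and uptake, 7 of 25 tested members rose and 1 fell (4 and 1 adjusted over the list alone, and with all genes adjusted 4 rises without control replicate 1, 3 rises without control replicate 2, 2 rises without lapatinib replicate 3, 0 falls without lapatinib replicate 2 and 2 falls without lapatinib replicate 3; adjusted p = 0.00691, adjusted p = 0.716 with an estimated correlation). The list call was lost without lapatinib replicate 3 (adjusted p = 0.597) and with the rotation test fry (adjusted p = 0.306). SC5D rose from 4.02 ± 0.926 to 12.4 ± 2.43 FPKM (log2 1.41) and INSIG1 from 12.7 ± 2.52 to 46.2 ± 28.0 FPKM (log2 1.66). INSIG1 stood at 26.4 and 66.0 FPKM in the lapatinib libraries, with log2 1.019 without lapatinib replicate 3 and adjusted p = 0.0569 with no filter. PMVK fell (−0.52; adjusted p = 0.1204 without lapatinib replicate 2). Of fatty acid synthesis genes, 4 of 9 tested members rose and 1 fell (4 and 1 adjusted over the list alone, and with all genes adjusted 2 rises without control replicate 1 and 2 falls without lapatinib replicate 3; adjusted p = 0.174; adjusted p = 0.00851 without lapatinib replicate 2). The desaturase gene SCD rose from 572 ± 118 to 1783 ± 30.1 FPKM (log2 1.66, adjusted p = 0.00178) and FASN from 53.3 ± 7.45 to 145 ± 52.98 FPKM (log2 1.39), while the elongase gene ELOVL6 fell from 12.1 ± 0.985 to 1.27 ± 0.366 FPKM (log2 −2.54, adjusted p = 0.000957).

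Keratinocyte genes changed gene by gene. Of suprabasal and cornified-layer genes, 6 of 13 tested members rose and 3 fell (6 and 3 adjusted over the list alone, and with all genes adjusted 3 rises without lapatinib replicate 2 and 1 fall without control replicate 1 or 2 or lapatinib replicate 2; adjusted p = 0.118). KRT1, a suprabasal keratin, rose from 0.1204 ± 0.0835 to 5.60 ± 4.23 FPKM (log2 2.39) and TGM1, which cross-links the cornified envelope, from 0.960 ± 0.364 to 5.17 ± 1.52 FPKM (log2 1.65, adjusted p = 0.00262). The transcription factor gene GRHL3 fell from 9.96 ± 3.00 to 1.86 ± 0.797 FPKM (log2 −1.93). GRHL1 (−0.57; adjusted p = 0.166 without lapatinib replicate 3) and OVOL1 (−0.46; log2 −0.28 and adjusted p = 0.258 without lapatinib replicate 2) fell less. Of basal keratinocyte genes, 4 of 15 tested members rose and 0 fell (4 and 0 adjusted over the list alone, and with all genes adjusted 2 rises without lapatinib replicate 2 and 1 fall without control replicate 3; adjusted p = 0.0639 by camera, adjusted p = 0.0107 as higher by fry, and by camera adjusted p = 0.0299 without lapatinib replicate 2). LAMB3 rose from 77.5 ± 8.63 to 218 ± 13.2 FPKM (log2 1.49, adjusted p = 0.00115), the integrin gene ITGB4 from 42.7 ± 4.03 to 86.6 ± 5.69 FPKM (log2 1.01). KRT15 rose from 235 ± 96.3 to 629.7 ± 56.6 FPKM (log2 1.52), with adjusted p = 0.102 without lapatinib replicate 2, and COL17A1 from 80.1 ± 2.21 to 108 ± 0.831 FPKM (log2 0.42), with adjusted p = 0.0946 without lapatinib replicate 2. Among stress and simple-epithelial keratins, 3 of 8 tested members fell and 2 rose (3 and 2 adjusted over the list alone, and with all genes adjusted 0 rises without lapatinib replicate 2 and 1 rise without lapatinib replicate 3; adjusted p = 0.847). KRT8 fell from 94.1 ± 6.36 to 39.0 ± 4.25 FPKM (log2 −1.25) and KRT18 from 75.5 ± 27.3 to 18.7 ± 0.798 FPKM (log2 −1.90). KRT6A fell from 318 ± 70.8 to 136 ± 56.9 FPKM (log2 −1.26), with log2 −0.82 and adjusted p = 0.0909 without lapatinib replicate 2. KRT7 (1.12; log2 0.75 and adjusted p = 0.113 without lapatinib replicate 2) and KRT19 (0.73; adjusted p = 0.0843 without lapatinib replicate 3) rose. Of epithelial junction genes, 7 of 22 tested members rose and 4 fell (7 and 4 adjusted over the list alone, and with all genes adjusted 4 rises without lapatinib replicate 2 or 3, 2 falls without control replicate 2 and 1 fall without lapatinib replicate 2; adjusted p = 0.0975). The tight junction gene CLDN1 rose from 83.4 ± 8.26 to 376 ± 65.7 FPKM (log2 2.15, adjusted p = 0.00111) and CLDN4 fell from 18.6 ± 2.49 to 2.32 ± 3.18 FPKM (log2 −3.00, adjusted p = 0.0110). CLDN4 stood at 0.0704 and 4.57 FPKM in the lapatinib libraries, with log2 −1.81 without lapatinib replicate 2 and adjusted p = 0.0509 with no filter. For mesenchymal and extracellular matrix genes, 3 of 12 tested members rose and 3 fell (3 and 3 adjusted over the list alone), with a median of 0.01, a mean of −0.01 and adjusted p = 0.690. TGFBI rose from 107 ± 8.02 to 256 ± 3.78 FPKM (log2 1.25) and PLAU from 37.1 ± 7.05 to 102 ± 27.4 FPKM (log2 1.43). SNAI2 rose from 7.59 ± 0.627 to 15.1 ± 0.728 FPKM (log2 0.91). PLAUR (−1.24) and ITGA5 (−0.76) fell.

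Among epidermal cytokines, chemokines and alarmins, 4 of 11 tested members rose and 4 fell (4 and 4 adjusted over the list alone), with a median of −0.14, a mean of 0.02 and adjusted p = 0.769. The alarmin gene S100A7 rose from 3.51 ± 2.77 to 30.4 ± 0.731 FPKM (log2 3.01, adjusted p = 0.00583) and LCN2 from 86.7 ± 26.4 to 289.6 ± 60.1 FPKM (log2 1.76). The adhesion molecule gene ICAM1 rose from 3.22 ± 0.0428 to 10.5 ± 0.988 FPKM (log2 1.44, adjusted p = 0.00112) and CCL2 from 0.483 ± 0.0830 to 1.81 ± 0.886 FPKM (log2 0.89), with log2 0.56 without lapatinib replicate 3 for CCL2 and adjusted p = 0.0590 with no filter. The interleukin-1 genes IL1A, from 8.19 ± 3.14 to 0.597 ± 0.218 FPKM (log2 −2.48, adjusted p = 0.00160), and IL1B, from 20.2 ± 4.36 to 2.00 ± 0.777 FPKM (log2 −2.83, adjusted p = 0.00112), fell, as did IL1RN (−0.97) and CXCL1 (−0.74; adjusted p = 0.0858 without lapatinib replicate 3). Of interferon-stimulated genes, 4 of 19 tested members fell and 2 rose (3 and 2 adjusted over the list alone, and with all genes adjusted 2 falls without control replicate 1 or lapatinib replicate 2; adjusted p = 0.907). USP18 fell from 9.11 ± 0.503 to 2.24 ± 0.622 FPKM (log2 −1.66) and OAS3 from 18.8 ± 1.19 to 8.77 ± 2.06 FPKM (log2 −1.03), and the interferon regulatory factor genes IRF7 (0.99) and IRF9 (1.36) rose. Markers of other cell types were mostly near the floor. No fibroblast or melanocyte marker reached the filter, and the highest were COL1A1 (0.324 ± 0.0674 FPKM in control and 1.13 ± 0.170 FPKM in lapatinib libraries) and PMEL (0.352 ± 0.0472 and 0.445 ± 0.0421 FPKM). Of the 11 leukocyte and endothelial markers 3 were tested, of which HLA-DRA did not pass. CD68, which also encodes a lysosomal protein of other cells, rose from 10.4 ± 2.57 to 24.98 ± 2.10 FPKM (log2 1.21), and CDH5 from 0.663 ± 0.463 to 10.03 ± 7.90 FPKM (log2 2.55). PTPRC stayed at or below 0.00920 FPKM in all 5 libraries.

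**Figure D3:**
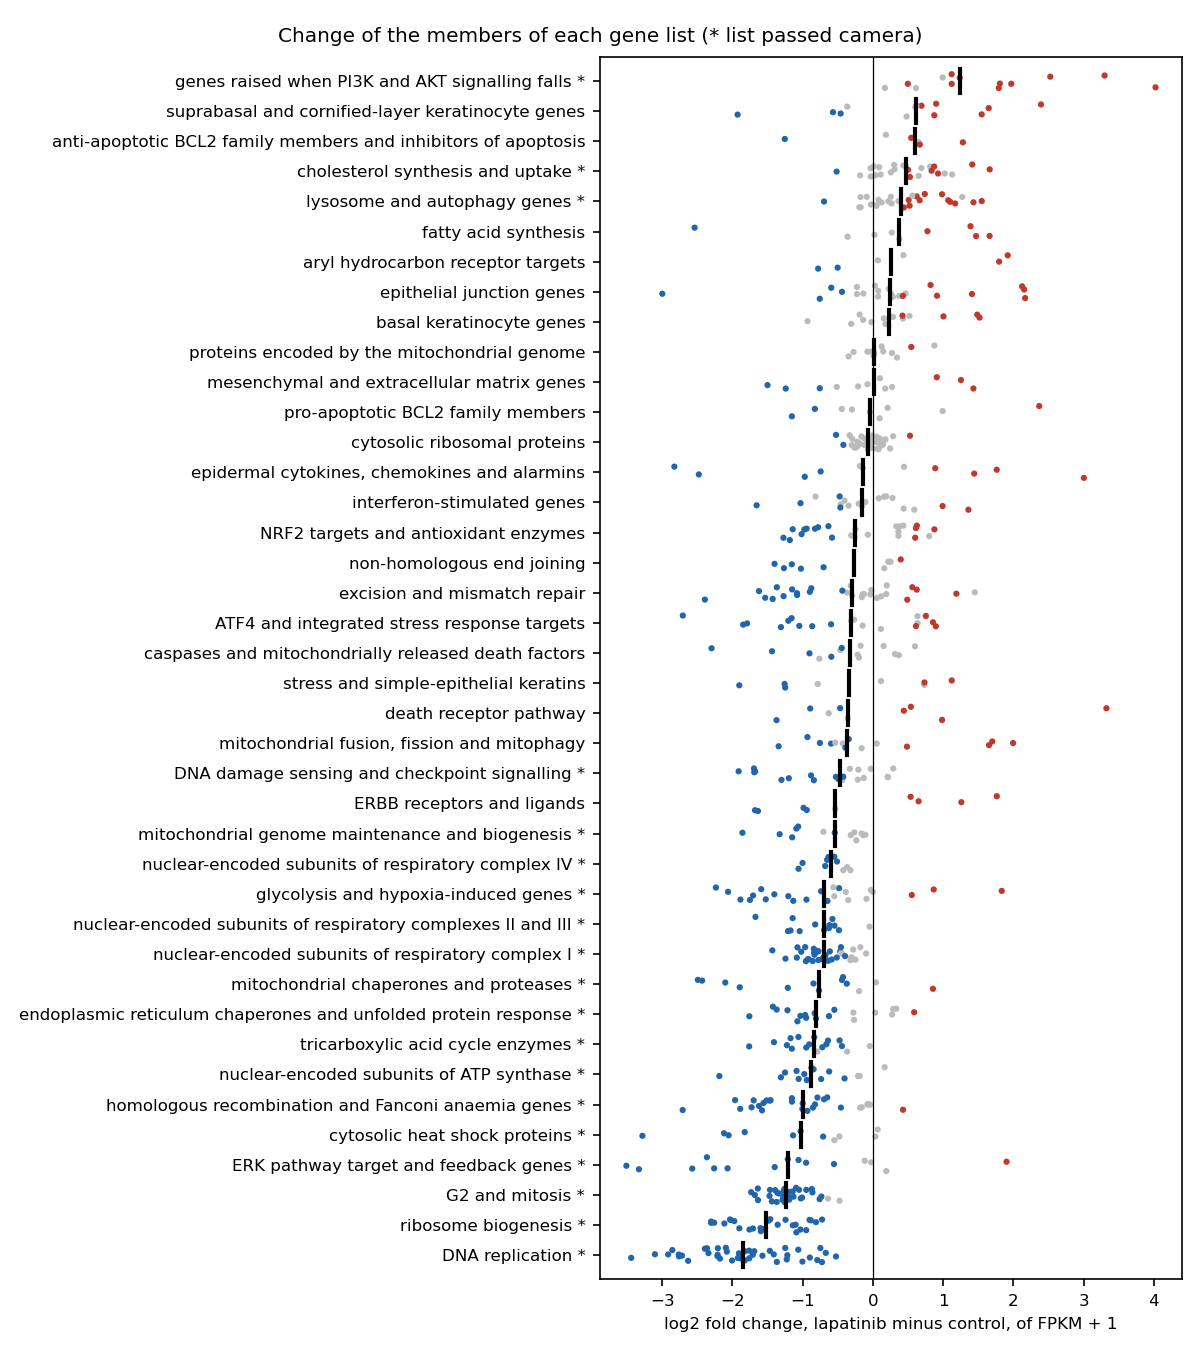
Log2 fold change of each tested member (points, red for rises and blue for falls that passed the test, grey for the rest) of the tested lists reported here, ordered by median (black bars), with an asterisk for lists that passed camera at the preset correlation. Medians ran from −1.85 for DNA replication to 1.24 for genes raised when PI3K and AKT signalling falls.

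Camera with its preset correlation called 19 of the 41 tested lists, 3 higher and 16 lower. With an estimated correlation it called 0, where the smallest unadjusted p, that of complex I, was 0.0265 (adjusted p = 0.502). That version rests on 3 residual degrees of freedom, so a lost call does not by itself show that members moved together. For basal keratinocyte genes the estimated correlation was −0.0227, below the preset 0.01, yet the unadjusted camera p went from 0.0311 to 0.105. The rotation test fry called 23 lists in 1 direction, among them 18 of the 19, and 41 as changed in either direction. Only the cholesterol list was called by camera and not by fry. Fry does not weigh a list against the other genes, and 45.2% of tested genes were called changed. Its calls therefore do not back those of camera.

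The largest rises among genes of at least 5 FPKM in the higher group were those of MMP13, a collagenase, from 2.25 ± 1.15 to 110.5 ± 81.0 FPKM (log2 4.94, adjusted p = 0.00151), and the long non-coding RNA LINC02518, from 0.291 ± 0.184 to 27.3 ± 16.1 FPKM (log2 4.33). PIK3IP1, above, and ATP6V1B1, a proton pump subunit, from 1.73 ± 1.00 to 42.4 ± 17.2 FPKM (log2 4.01), followed. TP53INP2, which acts in autophagy, rose from 2.42 ± 1.13 to 50.9 ± 10.1 FPKM (log2 3.97) and the extracellular chaperone gene CLU from 12.8 ± 3.67 to 225 ± 148 FPKM (log2 3.89). The alkaline phosphatase gene ALPP rose from 13.9 ± 1.15 to 230.3 ± 100.2 FPKM (log2 3.89). GBP2 rose from 1.17 ± 0.778 to 29.2 ± 12.3 FPKM (log2 3.80), SLURP2 from 1.44 ± 1.17 to 29.9 ± 1.84 FPKM (log2 3.79) and CLCA4 from 0.446 ± 0.291 to 24.0 ± 22.1 FPKM (log2 3.77). The largest falls were those of NME1-NME2, from 147 ± 13.8 to 15.5 ± 21.95 FPKM (log2 −4.71), with adjusted p = 0.0767 without control replicate 1, log2 −2.21 without lapatinib replicate 2 and log2 −7.21 without lapatinib replicate 3, and of the small nucleolar RNA SNORA18, from 23.6 ± 2.01 to 0.00195 ± 0.000235 FPKM (log2 −4.61). MALL fell from 62.2 ± 2.33 to 2.72 ± 1.29 FPKM (log2 −4.13, adjusted p = 0.000881) and MIR1244-2 from 108 ± 26.4 to 8.34 ± 5.54 FPKM (log2 −3.66). After DUSP6 and MCM6, above, came the transcription factor gene MYBL2, from 64.9 ± 18.3 to 5.99 ± 4.90 FPKM (log2 −3.40) and CALB2, which encodes calretinin, from 13.9 ± 3.78 to 0.433 ± 0.182 FPKM (log2 −3.35). FOSL1, above, and NME1, from 35.7 ± 7.03 to 2.63 ± 0.297 FPKM (log2 −3.32), came next. NME1 and NME1-NME2 share exons, ALPP has a near-identical paralog, and SNORA18 and MIR1244-2 lie in or resemble longer transcripts, so the reads behind these values cannot be assigned to them with certainty. Exons shared with another annotated gene on the same strand leave the values of AHR, ATF5, ATP6V1B1, BUB1B, CD68, CHEK1, CLU, COL17A1, ERBB3, GBP2, HSPA9, IRF9, KRT15, LAMB3, MCL1, MIEF1, NOP56, PINK1, SLC16A3 and SLURP2 uncertain in the same way. The same holds for ENO1, HSP90AB1, KRT18 and the ribosomal protein genes, which have near-identical copies elsewhere in the genome.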

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

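Alternatives with mitochondrial genes left out, protein-coding genes only or genes sharing exons left out were chosen after seeing the data. No alternative gave a changed gene the opposite sign. The number of changed genes was 3165 with a mean FPKM of at least 5, where only 6080 genes were tested, and lay between 4525 and 6545 under the other alternatives that kept all 5 libraries. Leaving out 1 library gave 2875 to 5066 changed genes, 1546 to 2073 genes changed at least 2-fold and 18 to 21 lists called by camera. The lowest count came without lapatinib replicate 2, where fewer samples remain and the lone lapatinib library is assumed to vary like the controls. The count of genes changed at least 2-fold by lapatinib was 760 with a pseudocount of 5, which shrinks the fold change of low genes, and 2610 with 0.1. Lists called numbered 0 with an estimated inter-gene correlation, which allows for members moving together but rests on only 3 residual degrees of freedom. Under the other alternatives with all libraries they numbered 19 to 23. The share of changed genes that were higher was 40.9% as reported, 48.9% with median-ratio rescaling, 48.6% with quantile normalization and 36.8% with TPM. Over all alternatives, named genes stayed on their side of the threshold in 4301 cases, lost a call in 243 and gained one in 5, and lists stayed in 819, lost a call in 22 and gained one in 14. The replicate number as a block gave 4756 changed genes with all 5 libraries in the fit. Control replicate 1 is the only library with its number, so it adds nothing to the group difference there. The median log2 fold change of tested genes was −0.0651 both in that fit and without control replicate 1. Control and lapatinib libraries share only the numbers 2 and 3, whose deviations correlated at 0.0885 and 0.0775. These are not separate checks, since the deviations of 2 lapatinib libraries mirror each other (control 2 with lapatinib 3, −0.0885). The labels do not say that equal numbers were handled together. DESeq2 and its count-based alternatives were not run, since the values are not counts. Lapatinib replicate 1 has no values here and is in none of the fits. The filter leaves genes with a mean under 1 FPKM untested here. With no filter 29998 genes were tested and 5358 changed, 48.6% of them higher, while 3930 of the 5308 genes called with the filter kept their call. The spread between these samples is not shown to be that between separate cultures.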

Other observations

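The gene families in this part, the genes named from them and the test against ribosomal protein genes were chosen only after the result was seen. FPKM of histone genes rose while those of the replication genes fell. Of 37 tested histone genes 27 rose and 3 fell, with a median log2 fold change of 0.94 (adjusted p = 8.68e-07 over 64 families by camera, 0.553 with an estimated correlation). H2BC5 went from 15.2 ± 3.30 to 92.5 ± 26.2 FPKM (log2 2.52, adjusted p = 0.00131), H2BC21 from 3.91 ± 0.908 to 22.4 ± 3.32 FPKM (log2 2.26, adjusted p = 0.00114), H2AW from 15.9 ± 1.83 to 69.7 ± 15.2 FPKM (log2 2.05, adjusted p = 0.00114) and H1-2 from 21.9 ± 2.47 to 74.3 ± 34.8 FPKM (log2 1.64, adjusted p = 0.00597). Over the scalings and left-out libraries the family median stayed between 0.77 and 1.201, and 16 members rose without lapatinib replicate 2. Histone genes resemble each other, so values of single members are uncertain. FPKM do not separate histone transcripts with a poly(A) tail from those without, so a rise in total histone RNA is not shown.

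Of the 64 families 16 passed camera, 3 higher and 13 lower, and 0 passed with an estimated correlation (1 at unadjusted p under 0.05). Among large mitochondrial ribosomal proteins (MRPL), 36 of 49 tested members fell and 0 rose (median −0.79, adjusted p = 4.19e-08), and among small ones (MRPS), 21 of 29 tested members fell and 0 rose (median −0.71, adjusted p = 8.63e-06). For the stem PSM, which holds the proteasome subunits, 35 of 47 tested members fell and 1 rose (median −0.79, adjusted p = 3.34e-06). For nucleoporins (NUP), 17 of 22 tested members fell and 0 rose (median −0.87, adjusted p = 3.95e-06). For cytosolic aminoacyl-tRNA synthetases, 12 of 17 tested members fell and 0 rose (median −0.82, adjusted p = 0.00268). With an estimated correlation these gave adjusted p = 0.546 for the first 4 and 0.604 for the synthetases. These 5 kept their direction and call under every scaling and with each library left out, but 13 MRPS members fell without either lapatinib library, and 8 synthetases. Of the other families, those of the stems DDX (0.000305), TIMM (0.00190), POLR (0.00213), COX (0.00615) and RAD (0.0228) passed as lower and TBC (0.0163) as higher. Calls of DHX, EIF and TRMT as lower and of ZNF as higher were lost under some scalings or without single libraries (highest adjusted p = 0.0827, 0.0827, 0.106 and 0.0827). The stems RPL (adjusted p = 0.645) and RPS (0.972), which hold the ribosomal proteins, did not pass. Neither did UBE (0.669), with the ubiquitin-conjugating enzymes, nor USP (0.437), with the ubiquitin-specific proteases. A stem takes in every symbol with those leading letters, so families such as RPS, PSM and UBE can hold other genes too.

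Nuclear-encoded respiratory chain subunits fell (median −0.69) while mitochondrially encoded ones did not (median 0.02). A larger share of mitochondrial transcripts in the FPKM total would lower all other genes alike. As deposited, the nuclear subunits lay −0.62 from the median of all tested genes. With mitochondrial genes left out the gap was −0.63, but that rescaling moves the remaining genes nearly alike and could hardly change it. After a spline of transcript length and GC content was removed, the gap was −0.59. A loss of short abundant transcripts would take the ribosomal protein genes along, and these lay 0.63 above the nuclear subunits. Genes of other processes fell as far, with medians of −0.69 for glycolysis, −0.81 for endoplasmic reticulum chaperones and −0.87 for nucleoporins. The fall was thus not particular to the respiratory chain. Of the 41 tested lists, camera called 16 lower and 3 higher. A lower output of nuclear genes for the respiratory chain after lapatinib stays open as a hypothesis. It was not itself tested, and the pattern was found on the same data as the tests above.

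Libraries of the same group were spread along the axis of the lapatinib response: on the first principal component, controls 1 to 3 stood at −28.5, −29.1 and −42.9 and lapatinib 2 and 3 at 56.95 and 43.6. Across genes, control 3 minus control 2 correlated at −0.22 with lapatinib 3 minus control 1, and control 2 minus control 1 at −0.07 with lapatinib 3 minus control 3. A smooth trend with annotated transcript length and GC content does not account for the place of control 3, since its correlation was −0.24 after the spline. Length and GC bias of another form was not tested, and the annotation behind the values is unclear. Cultures that differ in growth state may account for part of it, but the lists cannot single this out. The replication list lay 0.21 higher in control 3 than in the mean of controls 1 and 2, at percentile 99.98 of 10000 random lists. Ribosome biogenesis (0.49) and ERK target genes (0.32) were higher too. Suprabasal and cornified-layer genes (−0.29, percentile 0.12) and genes raised when PI3K and AKT signalling falls (−0.29, percentile 0.06) were lower. Cytosolic ribosomal proteins lay within the random lists (percentile 24.5). Replication genes move together (estimated correlation 0.591), unlike random genes, so other library differences could also place such a list outside. Mitotic genes were lower in control 3 (−0.21), whereas in lapatinib 2 minus lapatinib 3 the replication (−0.39) and mitosis lists (−0.72) were both lower, ribosome biogenesis was higher (0.11) and ERK target genes were level (0.02).

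For 118 tested genes (1.00%), 1 control library stood over 4-fold apart from the other 2, which lay within 1.5-fold of each other. Of these genes, 20 were called changed. Among them were CLCA4 (0.618, 0.611 and 0.110 FPKM in controls 1 to 3) and KRT1 (0.196, 0.134 and 0.0308 FPKM), both reported above as higher with lapatinib. B2M, the light chain of MHC class I, stood at 113, 95.3 and 6.46 FPKM in controls 1 to 3, and MYC at 2.82, 2.82 and 23.6 FPKM, and both passed as higher with lapatinib only without control replicate 3 (adjusted p = 0.0189 and 0.0119). Reads shared with an overlapping gene may explain part of these, as 40.0% of the genes with such a step and 16.9% of the others share exons on their strand (odds ratio 3.28, 95% interval 2.20 to 4.85, Fisher exact p = 4.91e-09), although B2M and MYC share none. Whether sampling noise of low genes contributes cannot be told apart, since genes of 10 FPKM or more had the step at 0.311 times the rate of lower genes. No biological explanation was tested.

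Of the 10 splits of the 5 libraries into 3 and 2, only 1, the real one, gave 5308 changed genes, and the highest count of any other split was 1. With 10 splits the share cannot go under 0.05. Every other split also mixes lapatinib and control libraries in a group, which widens the spread within it and holds its count down. The low counts of the other splits are therefore no check on the 5308.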
